A study of Mus musculus with 4 samples.

How the data were processed

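Single-cell RNA was measured in 4 mouse lung libraries at embryonic day 18.5, 2 labelled wild type and 2 labelled Dnmt1 CKO. The mutants carry Tbx4-rtTA, Tet-O-Cre and a deleted form of Dnmt1: a Tbx4-driven, doxycycline-dependent activator switches on Cre in the lung mesenchyme and Cre deletes part of Dnmt1, the maintenance DNA methyltransferase. The labels do not say whether each library came from a separate animal, so every p-value measures the spread between these 4 libraries. The deposited values are UMI counts per gene and barcode, and per the labels the authors made them from droplet 3′ libraries with bcl2fastq 2.20 and Cell Ranger 3.1.0 on GRCm38.p6 and later used Seurat. The lowest total in any deposited barcode was 500 UMIs. The files held 55471 gene identifiers, of which 54573 were found in the GENCODE vM21 annotation used for positions.

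The 4 libraries (wild type replicates 1 and 2, Dnmt1 CKO replicates 1 and 2) held 6698, 6284, 7013 and 7820 barcodes. Barcodes with fewer than 500 genes (1294, 1041, 2513 and 1910) and then those with over 20% mitochondrial UMIs (196, 436, 265 and 455) were left out. Haemoglobin transcripts took over 50% of the UMIs in 76.5%, 49.4%, 88.0% and 60.9% of the barcodes left out for few genes. Scrublet, with its automatic threshold and an expected rate of 6%, called 228, 172, 78 and 82 doublets, which were also left out. That left 5111, 4932, 4323 and 5675 cells, with medians of 5902, 7604, 7685 and 6115 UMIs. Counts were scaled to 10000 per cell and log-transformed in scanpy 1.11.5, without integration of the libraries. Sex-linked, haemoglobin and mitochondrial genes were kept out of the 2000 variable genes, and 30 principal components, 15 neighbours and Leiden clustering (leidenalg 0.10.2, resolution 1.0) followed. Each cluster was named from 31 marker lists, with at least 3 markers needed. The marker lists were fixed before the data were examined, whereas the score and margin that a name had to reach were set after the clusters were seen. The names carry "-like" since no independent label was available. A cluster that reached no name held 0.157%, 0.101%, 1.13% and 1.15% of the cells and was left out of the class comparisons.

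UMIs were summed over the cells of a class in each library. Genes were compared in 5 broad classes and in the mesenchymal, epithelial and endothelial subclasses with at least 20 cells in every library. They were not compared in erythroid-like, cardiomyocyte-like or megakaryocyte-like cells nor in the subclasses of immune-like cells, whatever their number of cells. Low-count genes were filtered with filterByExpr, TMM factors were computed, and the quasi-likelihood F-test of edgeR 4.0.16 (R 4.3.3, limma 3.58.1) compared Dnmt1 CKO with wild type, 2 libraries against 2. Genes at an adjusted p (Benjamini-Hochberg over the genes tested in a class) under 0.05 are called. Log2 fold changes are Dnmt1 CKO over wild type with a prior count of 2, and SE is the fold change over the square root of F. An exact two-sided permutation test of 2 against 2 cannot go below 0.333, so none is reported. With 2 libraries a side, 33.3% of unchanged genes have groups that do not overlap. Class shares were tested with edgeR on cell counts without TMM. The difference between the change in mesenchymal-like cells and that in epithelial-like or endothelial-like cells was tested as an interaction.

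The named genes were chosen by a rule. It takes Dnmt1 and, among called genes with an average log2 CPM of at least 4 and groups that do not overlap, the largest rises and falls: 12 each way in mesenchymal-like cells, 6 in the other broad classes, 3 in subclasses and interactions. Unnamed gene models are left out. Where fewer than 3 genes are called, the 3 with the smallest p are given too, and each gene list adds up to 4 members with the smallest adjusted p. The text names the examples with the smallest adjusted p first. The 24 gene lists and the marker lists, each with at least 5 tested genes, were tested with camera at a preset correlation of 0.01, and again with an estimated correlation and with fry. A fold against a group with no UMIs is a lower bound against 3 UMIs over that group. With 1 to 3 UMIs the ratio is given with its exact 95% counting interval. Such bounds and intervals cover counting error only, and the fitted fold changes of these genes depend on the prior count. For shares of cells with a UMI, cells were thinned to 3000 UMIs.

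The alternatives fixed before the data were examined were RLE or library-size scaling, no low-count filter, DESeq2 1.42.0, a replicate block, sex-linked genes left out, each library left out, stricter cell filters (1000 genes, 10% mitochondrial), doublets kept, Leiden resolutions of 0.5 and 2.0, equal cells per library, thinning to 2000 UMIs, TMM on cell counts, a denominator without erythroid-like and immune-like cells, and the other list tests. Chosen after seeing the data were sex as a covariate and clustering again without the genes called in mesenchymal-like cells.

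Each comparison was tested on simulated data with the same depths and spread. In mesenchymal-like cells 34.4% of genes set to change 2-fold and 84.4% of those set to change 4-fold were called, and 14 of 128 calls were false. The shares called at 4-fold were 68.0% in epithelial-like cells (7 of 85 calls false), 87.5% in endothelial-like (9 of 109), 82.6% in immune-like (16 of 107) and 87.9% in mesothelial-like cells (9 of 105). In the subclasses they were 82.5% for matrix fibroblast-like cells (6 of 108 false), 87.2% for adventitial fibroblast-like (6 of 132), 72.3% for myofibroblast-like (1 of 75), 89.6% for pericyte-like (3 of 113), 94.9% for alveolar type 1-like (8 of 131), 91.8% for alveolar type 2-like (7 of 123) and 27.6% for lymphatic endothelial-like cells (0 of 24). For the interactions they were 75.3% with epithelial-like (26 of 130 false) and 66.0% with endothelial-like cells (11 of 115). Among simulated lists with no change, camera at the preset correlation called 1 of 40 in immune-like cells and 0 in the other broad classes. Each gene was simulated independently of the others. These runs therefore cannot tell how often camera at the preset correlation calls falsely when genes of a list vary together.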

Results

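Cells of 4 late-gestation lung suspensions were compared, 2 wild type and 2 Dnmt1 CKO, to ask what loss of Dnmt1, directed to the lung mesenchyme, does to the cells of the organ. The deposited libraries held 48213065 and 56760219 UMIs in wild type replicates 1 and 2, and 49582593 and 54334468 UMIs in Dnmt1 CKO replicates 1 and 2. After filtering, 5111 and 4932 wild type cells and 4323 and 5675 Dnmt1 CKO cells fell into mesenchymal-like, epithelial-like, endothelial-like, immune-like and mesothelial-like classes, with small numbers of erythroid-like, cardiomyocyte-like and megakaryocyte-like cells. Wild type replicate 1 and Dnmt1 CKO replicate 2 were female by Xist and Y-linked transcripts, and the other libraries carried Y-linked transcripts, so each group held both sexes.

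Dnmt1 transcripts were lower in the mesenchymal-like and mesothelial-like cells of the mutant. In mesenchymal-like cells Dnmt1 (ENSMUSG00000004099.16, protein coding, chromosome 9, 20907209 to 20959888 on GRCm38.p6) averaged 26.6 ± 2.60 CPM in wild type and 10.98 ± 2.68 CPM in Dnmt1 CKO (SD, n = 2), a log2 fold change of -1.28 (SE 0.226, edgeR adjusted p = 0.00441). In mesothelial-like cells, the outer lining of the lung, the CPM values were 55.5 and 50.04 in wild type and 9.92 and 16.7 in Dnmt1 CKO, a log2 fold change of -1.93 (SE 0.374, adjusted p = 0.037). That call was lost without wild type replicate 1 (-1.86, adjusted p = 0.153) and without wild type replicate 2 (-2.02, adjusted p = 0.179), and also with DESeq2, the stricter cell filter and equal cells per library. Dnmt1 was not called in epithelial-like (-0.03), endothelial-like (-0.08) or immune-like cells (0.03). The test of the difference between classes was passed for mesenchymal-like against endothelial-like cells (-1.23 on the log2 scale, SE 0.204, adjusted p = 0.00322) and not for mesenchymal-like against epithelial-like cells. The labels do not say which part of Dnmt1 is deleted, and a 3′ tag outside it would not register the deletion, so the UMIs that remain do not show an intact transcript.

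**Figure D1:**
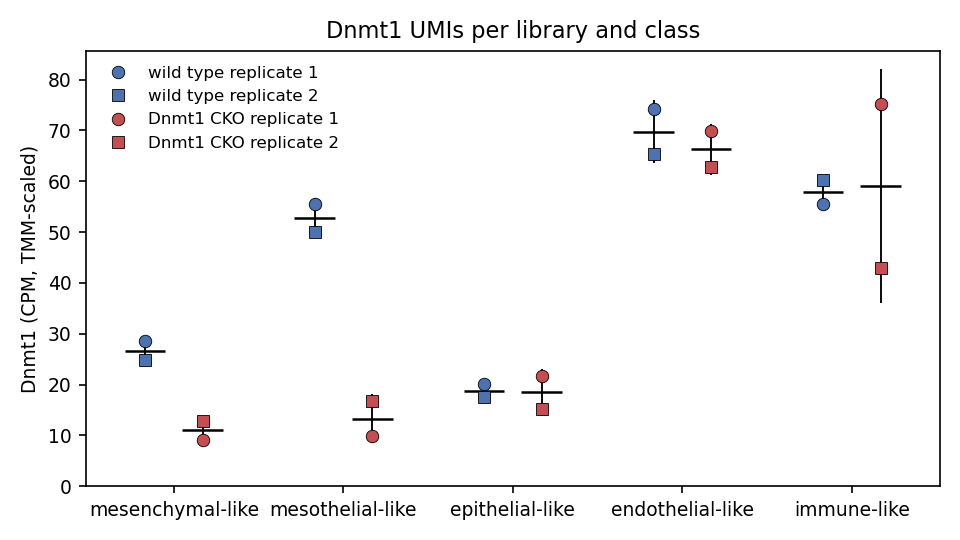
Dnmt1 CPM in the summed counts of each broad class, 1 point per library, with a horizontal line at the mean and a vertical line of 1 SD each way (n = 2 per group). In mesenchymal-like cells the wild type libraries lie at 28.5 and 24.8 CPM and the Dnmt1 CKO libraries at 9.09 and 12.9 CPM.

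Dnmt1 was not called in any of the 4 mesenchymal subclasses tested at Leiden resolution 1.0, and differences between subclasses were not tested. Most Dnmt1 CKO mesenchymal-like cells lay outside these subclasses. A cluster made up almost wholly of mutant cells (1240 and 1170 Dnmt1 CKO cells) held Dnmt1 at 5.35 and 4.17 CPM. Smooth muscle-like cells (319 and 267 Dnmt1 CKO cells), too few in wild type to be tested, held it at 2.91 and 2.63 CPM in Dnmt1 CKO. The subclass tests say nothing of these cells. In the adventitial fibroblast-like subclass Dnmt1 had a log2 fold change of -1.29 (adjusted p = 0.0592), which was called under 4 of 17 alternatives, among them without Dnmt1 CKO replicate 2 (-1.62, adjusted p = 0.011). In the matrix fibroblast-like clusters, it stood at 21.9 and 20.9 CPM in wild type and 26.1 and 19.99 CPM in Dnmt1 CKO, a log2 fold change of 0.06 (adjusted p = 0.991). In myofibroblast-like and pericyte-like cells the log2 fold change was -0.93 (adjusted p = 0.618) and -0.29 (adjusted p = 0.805). These values hung on the clustering. In myofibroblast-like cells Dnmt1 was called at Leiden resolutions of 0.5 (-2.40, adjusted p = 0.00131) and 2.0 (adjusted p = 0.00551), and in myofibroblast-like (-2.80, adjusted p = 0.00149) and pericyte-like cells (-1.05, adjusted p = 0.0176) when clustered without called genes. That pericyte-like class joined a cluster led by Higd1b (195, 165, 32 and 87 cells) with a cycling cluster led by Top2a (88, 36, 199 and 140 cells). Cycling cells made up most of its Dnmt1 CKO cells, so its value is not one of pericytes alone. The matrix fibroblast-like value hung on the clustering too: at Leiden resolutions of 0.5 and 2.0, where other cells carried the matrix fibroblast-like name, Dnmt1 fell by 1.504 (adjusted p = 0.00116) and 1.11 (adjusted p = 0.0299) on the log2 scale.

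No class was called for its share of the suspension by edgeR (0 of 8 broad classes and 0 of 11 subclasses called, 0 and 0 at an unadjusted p under 0.05). Endothelial-like cells made up 15.1 ± 1.97% of wild type and 7.90 ± 3.26% of Dnmt1 CKO cells (SD, n = 2; log2 -0.94, SE 0.46, adjusted p = 0.408). Immune-like cells made up 11.6 ± 0.538% and 18.1 ± 2.87% (0.64, SE 0.384, adjusted p = 0.408). Macrophage or monocyte-like cells made up 7.07 ± 0.132% and 13.2 ± 0.91% (0.90, SE 0.611, adjusted p = 0.368). Epithelial-like cells stood at 18.6 ± 0.92% and 17.3 ± 7.98%, and mesenchymal-like cells at 53 ± 2.03% and 52.9 ± 7.28%. Without Dnmt1 CKO replicate 2, 5 broad classes were called, among them endothelial-like (-1.44, adjusted p = 0.00285), epithelial-like (-0.68, adjusted p = 0.0242) and immune-like cells (0.79, adjusted p = 0.0187), and 6 subclasses. With TMM on cell counts the rise of immune-like cells was called (0.58, adjusted p = 0.0449). Suspensions had undergone red cell lysis, and shares of a dissociated organ need not match those in the tissue. Shares of the mesenchymal subclasses were not compared, since the clusters parted by genotype: a cluster led by Saa3, Dazl and Rpl39l held 2 and 1 wild type cells and 1240 and 1170 Dnmt1 CKO cells. Saa3 was chosen here after its values were seen.

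**Figure D2:**
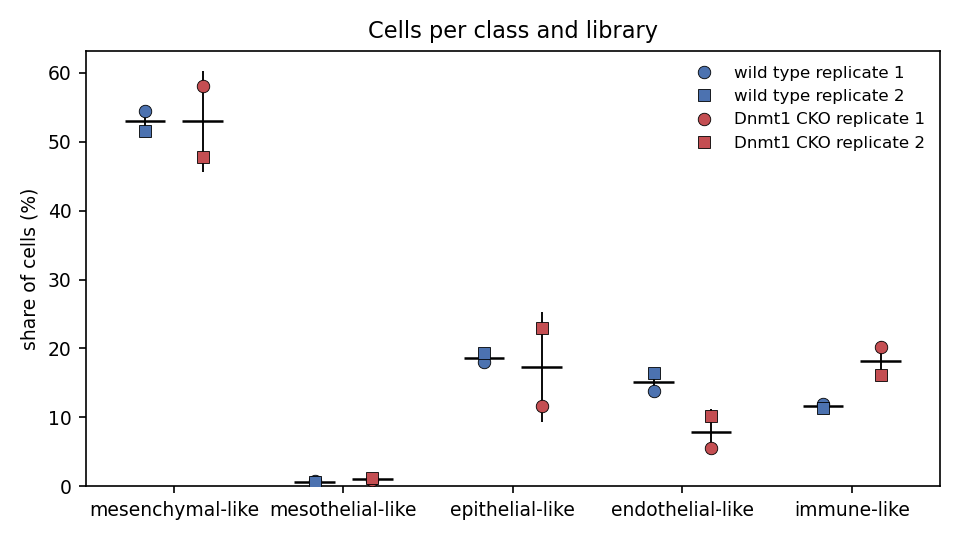
Percentage of the cells of each library in each broad class, 1 point per library, with a horizontal line at the mean and a vertical line of 1 SD each way (n = 2 per group). Endothelial-like cells average 15.1% in wild type and 7.90% in Dnmt1 CKO, and no class is called.

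The mesenchymal-like cells of the mutant switched on genes that wild type cells barely transcribed, among them genes of the germline. Dazl, an RNA-binding protein of germ cells, had 3 UMIs in both wild type libraries together and 18994 in Dnmt1 CKO, a ratio of 6447 (95% counting interval 2206 to 31266) and a fitted log2 fold change of 12.53 (SE 0.371, adjusted p = 6.82e-08). The testis tubulins Tuba3b and Tuba3a had no UMI in wild type and were at least 1184-fold and at least 419-fold higher. Their near-identical sequences can share reads. Tex101, a surface protein of spermatogenic cells, was at least 834-fold higher. Serpinb1c was at least 507-fold, Dcaf8l at least 468-fold and Fkbp6, needed for meiosis, at least 407-fold higher. The X-linked Trap1a rose by a ratio of 3186 (571 to 125893), Tex19.1 by 2172 (389 to 85832), the pregnancy glycoprotein gene Psg23 by 1434 (257 to 56672) and Taf7l by 1331 (455 to 6455). Rpl39l, the ribosomal protein paralogue of the testis, went from 0.183 and 0.0969 CPM to 245 and 182 CPM (log2 10.55, SE 0.374, adjusted p = 1.60e-07). All were higher in both Dnmt1 CKO libraries, and of them Serpinb1c was not called without wild type replicate 1 (adjusted p = 0.0566) or wild type replicate 2 (adjusted p = 0.0951).

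Among the genes chosen by the rule, Nppc, which encodes C-type natriuretic peptide, fell most (33.6 and 28.5 CPM in wild type, 1.10 and 2.09 in Dnmt1 CKO; log2 -4.30, SE 0.303, adjusted p = 7.99e-06). Abcd2, a peroxisomal fatty acid transporter, fell by 3.08 on the log2 scale, the membrane peptidase Mme by 2.95, the secreted glutathione peroxidase Gpx3 by 2.55, and Dtna by 2.43. The calcium sensor Vsnl1 fell by 2.38, the cGMP-dependent kinase Prkg2 by 2.36, the microtubule protein Mapt by 2.34 and the actin-binding Nebl by 2.23, followed by Sult5a1 (-2.12), the calcium channel subunit Cacnb4 (-2.12) and the matrix protease Adamts17 (-2.11). Not called without wild type replicate 1 were Abcd2 (-3.14), Mme (-3.15), Gpx3 (-2.20), Dtna (-2.51), Prkg2 (-2.39) and Adamts17 (-2.17). Not called without wild type replicate 2 were Abcd2 (-3.00), Mme (-2.71), Dtna (-2.35), Prkg2 (-2.33), Nebl (-2.02) and Adamts17 (-2.04). These sums take in cells of several kinds. Matrix fibroblast-like cells at Leiden resolution 1.0 numbered 1836 and 1685 in wild type and 126 and 448 in Dnmt1 CKO. Within them the falls were smaller, with log2 fold changes of -2.735 for Nppc, -1.83 for Mapt, -1.415 for Abcd2, -1.39 for Mme, -1.30 for Gpx3 and -1.11 for Prkg2. The other falls named here were not called there. The Dnmt1 CKO cells in these clusters were those that grouped with wild type cells. They held Dnmt1 at 26.1 and 19.99 CPM, against 21.9 and 20.9 CPM in wild type. The smaller falls may therefore come from which cells were grouped there, and do not show the size of the change in other mutant cells. A change in the mix of cells was not told apart from a change per cell. In all, edgeR called 2270 of 16106 genes in mesenchymal-like cells, 1248 up and 1022 down (2152 by DESeq2), from 16801888 to 20107825 UMIs per library. Of the genes tested, 58.1% had groups that did not overlap, against 33.3% by chance. The count was 1180 without wild type replicate 2, 1344 without Dnmt1 CKO replicate 1 and 1477 with sex as a covariate.

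Of 38 tested members of the list of methylation-silenced germline genes, 31 rose and 0 fell (33 and 0 adjusted over the list alone), with a median log2 fold change of 6.82, or 6.46 with the 21 genes at or under the floor set at their bound. Besides Dazl, Tex19.1 and Tex101, the list holds Slc25a31, the ADP/ATP carrier of the male germline, which rose by 8.32 (SE 0.355, adjusted p = 2.82e-07). The list was called by camera (adjusted p = 1.69e-33) and by fry (0.00544), with adjusted p = 0.458 with an estimated correlation. Summed over the 31 germline genes that rose there, mesenchymal-like cells held 4.50 and 8.55 CPM in wild type and 1530 and 1363 CPM in Dnmt1 CKO. The same sum in the classes not targeted was 24.4 and 27.6 CPM in Dnmt1 CKO epithelial-like, 18.3 and 62.6 CPM in endothelial-like and 32.4 and 29.4 CPM in immune-like cells, against at most 4.56 CPM in wild type.

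**Figure D3:**
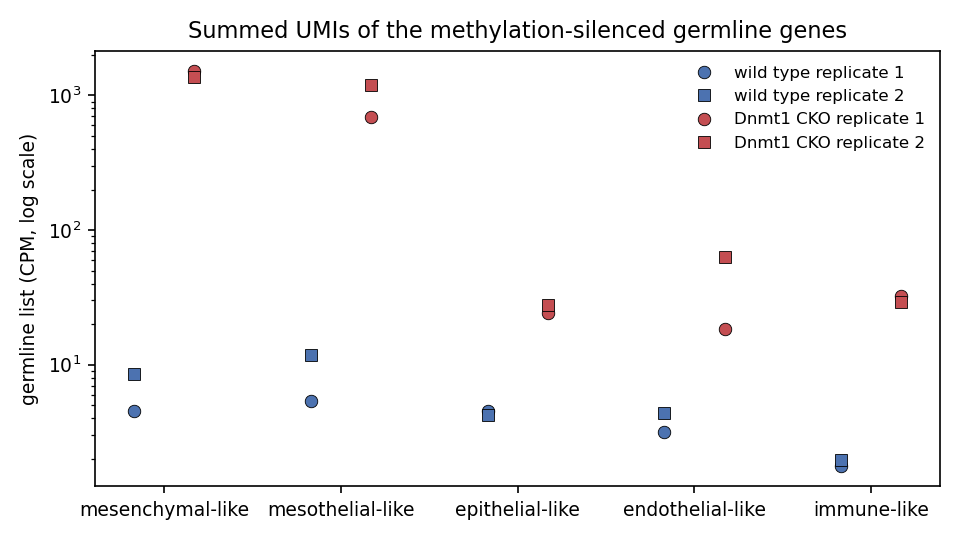
Summed CPM, in each class, of the 31 germline genes called up in mesenchymal-like cells, on a log axis, 1 point per library. Mesenchymal-like cells of the 2 Dnmt1 CKO libraries lie at 1530 and 1363 CPM, and those of wild type at 4.50 and 8.55 CPM.

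Imprinted genes moved both ways, with 10 of 30 up and 3 down (11 and 5 over the list alone, median 0.46, camera adjusted p = 0.116). H19, a maternally expressed non-coding RNA, rose by 1.44 (SE 0.226, adjusted p = 0.00235), whereas Igf2r fell by 1.34 (adjusted p = 0.00179), Grb10 by 1.09 (0.0043) and Zim1 by 1.65 (0.00401), the last not called without wild type replicate 2 (-1.38, adjusted p = 0.0579). Of 20 genes of the DNA methylation machinery, 1 rose and 1 fell (1 and 1 over the list alone, median -0.11, camera adjusted p = 0.528). These were Dnmt1 and the chromatin remodeller Hells, which rose by 1.73 (adjusted p = 0.0036) and was not called without wild type replicate 1 (1.87) or wild type replicate 2 (1.60). Uhrf1, the partner of Dnmt1 at replicated DNA, had a log2 fold change of 1.14 (adjusted p = 0.0679), and was called without Dnmt1 CKO replicate 2 (1.54).

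In the sums of mesenchymal-like cells some p53 targets and cell cycle genes rose, and none of those tested was called lower. Whether single cells held both was not examined. A cycling cluster held 83 and 23 wild type and 211 and 152 Dnmt1 CKO cells. A change in the mix of cells was thus not told apart from a change per cell. Of 28 p53 targets 11 rose and 0 fell (11 and 0 over the list alone, median 0.44, camera adjusted p = 0.00515, 0.881 with an estimated correlation, fry 0.0224). The stress cytokine Gdf15 rose by 4.38 (SE 0.315, adjusted p = 8.20e-06), the cell cycle inhibitor Cdkn1a by 1.53 (SE 0.217, 0.00127) and the death-promoting Bbc3 by 1.38 (SE 0.222, 0.00269). Of 17 apoptosis effectors 4 rose and 0 fell (6 and 0 over the list alone, median 0.40, camera adjusted p = 0.0643, fry 0.0464), Bbc3 being among them. Of 32 genes of G2 and M phase 23 rose and 0 fell (31 and 0 over the list alone, median 1.04, camera adjusted p = 5.44e-10), including Ccnb1 (1.47, SE 0.257, adjusted p = 0.00435) and Top2a (1.21, SE 0.234, 0.0073), the latter not called without wild type replicate 2 (1.03, 0.0783). Of 30 S phase genes 7 rose and 0 fell (21 and 0 over the list alone, median 0.79, camera adjusted p = 2.11e-06), with Mcm3 at 1.32 (SE 0.24, 0.00536). With an estimated correlation both cell cycle lists had an adjusted p = 0.881, and by fry 0.363 for S phase and 0.351 for G2 and M phase. At 3000 UMIs per cell, 5.70 ± 1.34% of wild type and 11.6 ± 2.29% of Dnmt1 CKO mesenchymal-like cells held a Mki67 or Top2a UMI (SD, n = 2), against 2.04 ± 1.38% and 1.98 ± 1.84% of alveolar type 1-like cells, taken as background. In neutrophil-like cells, also taken as background, the shares were 11.3 ± 4.21% and 0.0 ± 0.0%, from 7 and 12 wild type and 6 and 3 Dnmt1 CKO cells deep enough. The mesenchymal-like difference of 5.90 percentage points was 9.06 before thinning. At 3000 UMIs the share was also higher in Dnmt1 CKO endothelial-like cells, at 22.0 ± 4.37% in wild type and 30.0 ± 5.47% in Dnmt1 CKO. It was 3.99 ± 0.813% and 4.86 ± 0.52% in epithelial-like and 21.0 ± 0.919% and 21.0 ± 6.14% in immune-like cells. At 2000 UMIs the shares were 18.4 ± 2.02% and 22.5 ± 6.75% in endothelial-like and 4.29 ± 1.16% and 9.64 ± 2.3% in mesenchymal-like cells. None of these differences was tested, so whether a higher share was confined to mesenchymal-like cells was not settled.

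Of 12 matrix fibroblast markers 8 fell and 0 rose (10 and 0 over the list alone, median -1.11, camera adjusted p = 7.83e-06). Of 12 pericyte markers 6 fell and 1 rose (8 and 1 over the list alone, median -1.06, adjusted p = 0.00274). Of 12 myofibroblast markers 4 fell and 1 rose (5 and 1 over the list alone, median -0.63, adjusted p = 0.0239), a call lost without wild type replicate 1 (adjusted p = 0.101) and without Dnmt1 CKO replicate 1 (0.071). Of 11 adventitial fibroblast markers 3 rose and 3 fell (3 and 3 over the list alone, median 0.17, adjusted p = 0.722). Of 5 skeletal muscle markers 3 rose (3 over the list alone, median 1.78, adjusted p = 0.00452). With an estimated correlation each of these 5 lists had an adjusted p = 0.881. The sums cover all mesenchymal-like cells, whose clusters parted by genotype. A change in the mix of cells was therefore not told apart from a change per cell. Of 13 lipofibroblast genes 4 fell and 0 rose (5 and 1 over the list alone, median -0.56, adjusted p = 0.136, and 0.0366 without Dnmt1 CKO replicate 2), led by Tcf21, a transcription factor of lung fibroblasts (-1.39, SE 0.232, adjusted p = 0.00337). Of 19 contractile smooth muscle genes 3 fell and 0 rose (3 and 1 over the list alone, median -0.15, adjusted p = 0.699), with Itga8 at -1.28, not called without wild type replicate 2 (-0.81).

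Matrix genes were split. Of 25 collagens and matrix genes 3 rose and 6 fell (4 and 8 over the list alone, median -0.21, camera adjusted p = 0.303). The small proteoglycans Lum and Dcn rose by 2.48 (SE 0.188, adjusted p = 1.24e-05) and 1.72 (SE 0.203, 0.000389) and Fbln1 by 1.24, whereas Col14a1 fell by 1.12 (SE 0.197, 0.00439). Of 17 elastic fibre genes 1 rose and 2 fell (2 and 3 over the list alone, median -0.01, while camera's direction was up, adjusted p = 0.99). Fbn2, a fibrillin of the embryo, rose by 1.09 (SE 0.192, 0.00435). Mfap4 fell by 1.17 (0.0127), a call lost without wild type replicate 1 (-1.001) and without Dnmt1 CKO replicate 1 (-0.90). Tropoelastin, Eln, fell by 1.00 (0.0354), lost without the same libraries (-0.69 and -0.73).

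Signalling genes went both ways. Of 22 Wnt pathway genes 3 rose and 5 fell (7 and 9 over the list alone, median -0.10, camera adjusted p = 0.792), with Lef1 at -1.61 (SE 0.214, adjusted p = 0.00085), Wnt2 at -1.18 (0.00305) and Wnt11 at 1.55 (0.00234). Of 18 Fgf and Pdgf pathway genes 5 fell and 0 rose (7 and 0 over the list alone, median -0.34, adjusted p = 0.0682), among them the feedback inhibitor Spry4 (-1.14, SE 0.184, 0.00274). The list was called without wild type replicate 2 (adjusted p = 0.0457) and without Dnmt1 CKO replicate 2 (0.0205). Of 13 Hedgehog pathway genes 1 rose and 1 fell (1 and 1 over the list alone, median 0.36, adjusted p = 0.44), the fall being that of the ligand-binding Hhip (-1.50, SE 0.26, 0.00415), not called without wild type replicate 2 (-1.35). Of 22 Tgf-beta and Bmp pathway genes 2 fell and 0 rose (2 and 0 over the list alone, median 0.10, adjusted p = 0.99), with Tgfbr2 at -0.87, not called without wild type replicate 2 (-0.82) or Dnmt1 CKO replicate 1 (-0.64), or with sex as a covariate (-0.89). Of 18 hypoxia genes 1 rose and 5 fell (1 and 6 over the list alone, median -0.24, adjusted p = 0.104, and 0.0258 without wild type replicate 2), led by Bnip3 (-1.49, SE 0.238, 0.00277), not called without wild type replicate 2 (-1.35).

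Of 24 interferon response genes 5 rose and 1 fell (5 and 1 over the list alone, median -0.33, camera adjusted p = 0.982, with fry's direction up). The chemokine Cxcl10 rose by 2.32 (SE 0.343, adjusted p = 0.00279). Of 18 Hox genes 7 rose and 0 fell (7 and 1 over the list alone, median 0.03, adjusted p = 0.135, and 0.0457 without wild type replicate 2). Hoxc6 had no UMI in wild type and was at least 28.5-fold higher, and Hoxb9 rose by a ratio of 31.9 (10.6 to 157). Of 81 cytosolic ribosomal proteins 5 rose and 0 fell (5 and 0 over the list alone, median 0.05, adjusted p = 0.464), among them Rpl39l, Rps4l (1.70, adjusted p = 0.000568) and Rpl10l, which had no UMI in wild type and was at least 14.3-fold higher. Of 44 clustered protocadherins 1 rose and 2 fell (0 and 2 over the list alone, median 0.15, adjusted p = 0.792, and 0.0401 without wild type replicate 2). Of 18 dissociation stress genes 1 rose (1 over the list alone, median -0.01, while camera's direction was up, adjusted p = 0.85). None of 6 haemoglobins was called (0 over the list alone, median 0.89, adjusted p = 0.44), and with Dnmt1 CKO replicate 2 left out Hbb-bt (1.503), Hbb-bs (1.43), Hba-a2 (1.32) and Hba-a1 (1.36) were called, as they were without the low-count filter. None of 15 mitochondrially encoded genes (0 over the list alone, median 0.07, while camera's direction was down, adjusted p = 0.982) and none of 6 sex-linked genes was called (0 over the list alone, median -0.26, while camera's direction was up, adjusted p = 0.782). Without wild type replicate 1, the female wild type library, mt-Nd6 (-1.01), Xist and Tsix were called, and without wild type replicate 2 Tsix (1.07). In all, 8 of 48 lists were called in mesenchymal-like cells, 5 up and 3 down, and 0 with an estimated correlation, where 1 list lay at an unadjusted p under 0.05. By fry 3 were called. The count was 13 without wild type replicate 2 and 13 without Dnmt1 CKO replicate 1.

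**Figure D4:**
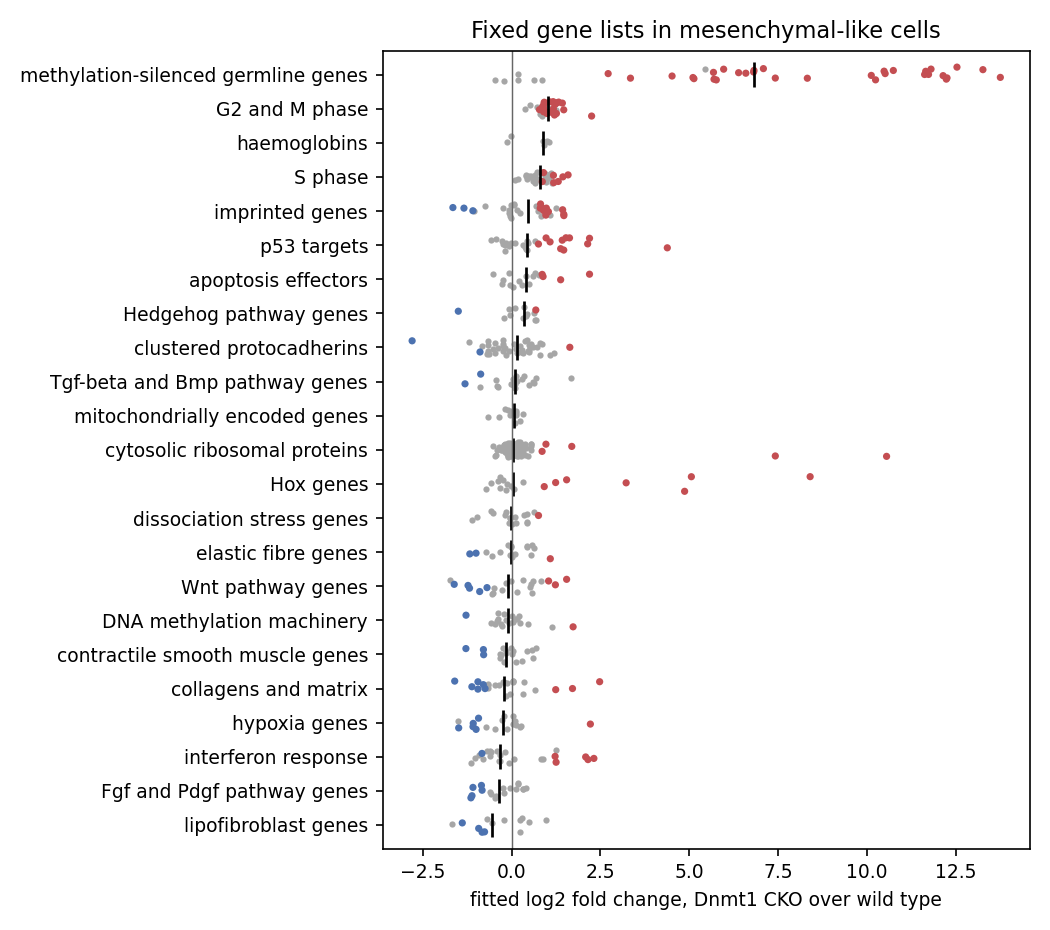
Fitted log2 fold change, Dnmt1 CKO over wild type, of each tested gene of 23 gene lists in mesenchymal-like cells, with called rises in red, called falls in blue, other genes in grey and a black line at each list's median; sex-linked genes are left out. The germline list has a median of 6.82, and the other medians lie between -0.56 and 1.04.

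The 3 matrix fibroblast-like clusters together held 1836 and 1685 wild type and 126 and 448 Dnmt1 CKO cells. Among genes with an average log2 CPM of at least 4, Mfap5 (3.41, SE 0.313, adjusted p = 1.01e-06), Nnat, an imprinted gene (3.37), and Igf1 (3.01) rose most there, and Nppc (-2.74), Trf (-2.33) and the protease inhibitor A2m (-2.02) fell most. Some called genes below that level rose or fell more, among them Rpl39l (0.269 and 0.073 CPM in wild type, 48.8 and 11.8 in Dnmt1 CKO; log2 7.24), chosen after its values were seen. In the adventitial fibroblast-like cluster (158, 200, 392 and 346 cells), Dazl was at least 367-fold, Rpl39l at least 175-fold and Taf7l at least 96.5-fold higher. Lamc3 fell by 2.79, Aox3 by 2.54 and Sult1a1 by 2.16. Of these Lamc3 (-2.66) and Sult1a1 (-2.06) were not called without wild type replicate 1, nor Lamc3 (-2.90), Aox3 (-1.92) and Sult1a1 (-2.25) without wild type replicate 2. In the pericyte-like cluster (220, 186, 109 and 135 cells) Dazl was at least 297-fold, Rpl39l at least 98.2-fold and Tuba3b at least 76.9-fold higher. Hhip fell by 3.57, Edn3 by 2.99 and Lipg by 2.78. Not called were Rpl39l and Hhip (-2.83) without wild type replicate 1, Rpl39l and Edn3 (-2.64) without wild type replicate 2, and Edn3 (-2.27) without Dnmt1 CKO replicate 1. In the myofibroblast-like cluster (387, 347, 62 and 121 cells) Aspn rose by 3.03, Smim41 by 2.61 and Mnd1 by 2.47. Igfbp3 fell by 4.55 (SE 0.548, adjusted p = 0.00462). Pcdh20 and Sorcs1 were lower there by ratios of 15.8 (4.29 to 132) and 13.4 (4.50 to 65.6), the former not called without Dnmt1 CKO replicate 2 and neither called without wild type replicate 2. Mnd1 was not called without Dnmt1 CKO replicate 1 (1.66). Smim41 was not called with doublets kept (0.62), equal cells per library (3.67), sex as a covariate (2.61), Leiden resolutions of 0.5 (1.23) and 2.0 (1.08) or clustering without called genes (2.01), nor Aspn under the last 3 (1.88, 3.21 and 3.47). Sex as a covariate also ended the calls of Mnd1, Pcdh20 and Sorcs1, DESeq2 those of Pcdh20, Sorcs1, Hhip and Edn3, equal cells per library those of Pcdh20 and A2m, Leiden resolution 2.0 those of Mfap5 and Sult1a1, and clustering without called genes those of Lamc3 and Sult1a1.

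By edgeR 87 genes were called in matrix fibroblast-like (51 up, 36 down), 388 in adventitial fibroblast-like (203 up, 185 down), 34 in myofibroblast-like (21 up, 13 down) and 266 in pericyte-like cells (153 up, 113 down). Without wild type replicate 1 these counts were 398, 132, 265 and 158. Without wild type replicate 2 they were 192 in matrix fibroblast-like, 32 in adventitial fibroblast-like and 70 in pericyte-like cells. Without Dnmt1 CKO replicate 1 they were 58 in myofibroblast-like and 73 in pericyte-like cells, and without Dnmt1 CKO replicate 2, 195 in matrix fibroblast-like and 193 in myofibroblast-like cells. Since clusters parted by genotype, the cells compared under 1 name may differ in kind between the groups.

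Mesothelial-like cells (37, 28, 39 and 67 cells), like mesenchymal-like cells, switched on germline and X-linked homeobox genes. The homeobox genes Rhox5, Rhox6 and Rhox10 had no UMI in wild type and were at least 68.3-fold, 44.6-fold and 36.0-fold higher. Members of this family resemble each other in sequence. The acute-phase gene Saa3 was at least 58.1-fold, Dpep3 at least 33.1-fold and Taf7l at least 31.6-fold higher. Itih5 fell by 2.59, Celf4 by 2.36 (SE 0.305, adjusted p = 0.00273), Gpx3 by 2.06, the muscarinic receptor Chrm2 by 2.05, Thbd by 2.01 and the growth factor Igf2 by 1.95. Not called without wild type replicate 1 were Itih5 (-2.67) and Gpx3 (-1.89). Not called without wild type replicate 2 were Dpep3, Itih5 (-2.53), Gpx3 (-2.25), Chrm2 (-1.49), Thbd (-1.70) and Igf2 (-1.70). With equal cells per library Itih5, Gpx3, Chrm2, Thbd and Igf2 were not called, with DESeq2 Itih5 and Thbd, and with the stricter cell filter Saa3 and Chrm2. Library-size scaling also ended the call of Chrm2. Of 14 germline genes tested 10 rose and 0 fell (13 and 0 over the list alone), with a median of 8.30, or 4.44 with all 14 at their bound (camera adjusted p = 1.32e-32, 0.542 with an estimated correlation). The collagens and matrix list was also called, with a median of -0.69 (adjusted p = 8.73e-08, 0.542 with an estimated correlation). So were the mesenchymal markers in these cells, with a median of -0.90 (adjusted p = 1.81e-06, 0.542 with an estimated correlation), and their summed CPM was 14530 and 16550 in wild type and 8639 and 6758 in Dnmt1 CKO. In all 64 of 8762 genes were called, 44 up and 20 down, from 555440 to 1268322 UMIs per library. The count was 37, 14, 222 and 111 without wild type replicates 1 and 2 and Dnmt1 CKO replicates 1 and 2. Of 30 lists 10 were called (16 without either Dnmt1 CKO library).

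Epithelial-like cells, which the driver is not meant to target, had no called gene in edgeR (0 of 15276, 473 at an unadjusted p under 0.05, 20 by DESeq2), from 8954026 to 19701176 UMIs per library. The smallest p were those of the neutrophil gene S100a9 (-4.19, SE 0.454), Dazl (1 wild type and 198 Dnmt1 CKO UMIs, a ratio of 214, 37.9 to 8488) and the chemokine Ccl20 (3.75, SE 0.453), each with an adjusted p = 0.126. They were called without Dnmt1 CKO replicate 1 (S100a9 -4.74, Ccl20 3.73), without Dnmt1 CKO replicate 2 (-3.62 and 3.80), by DESeq2 and without the low-count filter, S100a9 also with equal cells per library and Dazl with doublets kept. The count was 2 without wild type replicate 1, 65 without Dnmt1 CKO replicate 1 and 81 without Dnmt1 CKO replicate 2. By camera 21 of 46 lists were called (5 up, 16 down; 11 without wild type replicate 1, 12 without Dnmt1 CKO replicate 1), 0 of them with an estimated correlation, where 2 lay at an unadjusted p under 0.05 and each adjusted p was at least 0.656, and 0 by fry. The smallest p was that of 14 germline genes, of which 0 were called (6 up and 0 down over the list alone), with a median of 0.95 (adjusted p = 7.76e-10, 0.656 with an estimated correlation, fry 0.0999). Markers of other classes were also among them: the medians were -0.95 for 11 endothelial markers (adjusted p = 1.37e-08) and -0.54 for 12 matrix fibroblast markers (3.38e-06). The Fgf and Pdgf pathway list (18 genes, 0 called) had a median of -0.26 (0.00011), and the alveolar type 1 markers (11 genes, 0 called) -0.34 (0.00075). Alveolar type 1-like cells were 467 of 919 and 471 of 951 epithelial-like cells in wild type and 187 of 504 and 462 of 1302 in Dnmt1 CKO. That mix shifted the same way as their markers, so a change per cell was not told apart from it.

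In alveolar type 1-like cells, the thin cells of gas exchange, 9 of 10195 genes were called, 5 up and 4 down. Emb rose by 2.10 (SE 0.289, adjusted p = 0.00189), Ppp1r14c by 1.38 and Sprr1a by 1.38, and the neutrophil genes S100a9 and S100a8 fell by 4.90 and 3.95. Of these Emb, Ppp1r14c, Sprr1a and S100a8 were not called without wild type replicate 1 (2.35, 1.55, 1.38 and -4.01) or wild type replicate 2 (1.87, 1.22, 1.37 and -3.88), nor Sprr1a without Dnmt1 CKO replicate 1 (1.11). The same 4 genes were not called with sex as a covariate, nor Sprr1a with equal cells per library. The other called falls were Cstdc5 and Cstdc4. Each gene called down is among the leading genes of the neutrophil-like cluster at Leiden resolutions of 0.5 and 2.0. Neutrophil-like cells made up 0.874 ± 0.175% of wild type and 0.5 ± 0.209% of Dnmt1 CKO cells, a share that was not called. Whether these falls came from neutrophil RNA was not tested. Saa3, with an average log2 CPM under 4, was called too, at 0 and 0.311 CPM in wild type and 6.32 and 12.97 CPM in Dnmt1 CKO. In alveolar type 2-like cells, the surfactant producers, 4 of 13529 genes were called, all up, with Cbr2 at 1.49 (SE 0.24, adjusted p = 0.0372), a call lost without wild type replicate 1 (1.69) and wild type replicate 2 (1.31) and at Leiden resolution 0.5 (1.45). The other called genes, also under 4, were Ehf (2.10) and the germline transcripts Dazl (0.0987 and 0 CPM in wild type, 4.32 and 6.42 in Dnmt1 CKO) and Rpl39l (0 and 0 CPM, 2.235 and 2.33). Without wild type replicates 1 and 2 and Dnmt1 CKO replicates 1 and 2 the counts were 2, 1, 41 and 131 in type 1-like and 0, 0, 37 and 133 in type 2-like cells.

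In endothelial-like cells 12 of 12693 genes were called, 10 up and 2 down. Ccl21a, a chemokine of lymphatic vessels, rose by 1.71 (SE 0.27, adjusted p = 0.0128) and the fatty acid-binding Fabp4 by 1.63 (0.0478), while St6galnac5 fell by 2.21 (0.0079) and the fibroblast gene Col14a1 by 1.48 (0.0295). Without wild type replicate 2 none of the 4 was called (1.68, 2.14, -2.12 and -1.36), nor were Ccl21a (1.74), Fabp4 (1.26) and Col14a1 (-1.59) without wild type replicate 1, or Ccl21a (1.41) and Col14a1 (-1.28) without Dnmt1 CKO replicate 1. Ccl21a, Fabp4 and Col14a1 were not called with sex as a covariate or equal cells per library, Ccl21a and Fabp4 at Leiden resolution 0.5, and Fabp4 with RLE or library-size scaling or the stricter cell filter. Called with an average log2 CPM under 4 were, among others, Igfbp5 (3.09) and the testis gene Rpl39l (0 and 0.111 CPM in wild type, 4.65 and 7.36 in Dnmt1 CKO). Genes under that level were chosen here and in the alveolar subclasses after their values were seen. The count was 0 without wild type replicate 2, 101 without Dnmt1 CKO replicate 1 and 85 without Dnmt1 CKO replicate 2. Of 42 lists 9 were called (24 without Dnmt1 CKO replicate 2), 0 with an estimated correlation, where 2 lay at an unadjusted p under 0.05 and each adjusted p was at least 0.906, and 0 by fry. The medians were 1.16 for 8 lymphatic endothelial markers (adjusted p = 2.54e-07), 0.92 for 9 immune markers (1.24e-07) and -0.88 for 12 pericyte markers (9.03e-11). Lymphatic endothelial-like cells were 43 of 703 and 42 of 816 endothelial-like cells in wild type and 20 of 242 and 65 of 579 in Dnmt1 CKO. That mix shifted the same way as Ccl21a and the lymphatic markers, so a change per cell was not told apart from it. The S phase list had a median of 0.46 (1.24e-07) and was not called without wild type replicate 2 (0.239) or Dnmt1 CKO replicate 1 (0.473). In lymphatic endothelial-like cells (43, 42, 20 and 65 cells, from a cluster of which 34.6% were called doublets before filtering) 0 of 4790 genes were called by edgeR, 137 lay at an unadjusted p under 0.05, and DESeq2 called 0. The smallest p were those of Mfap4 (-2.04), Lbh (-2.43) and Npr3 (-2.69), each with an adjusted p = 0.151. All 3 were called without wild type replicate 1 (-2.26, -2.50 and -2.98), with doublets kept and without the low-count filter, and Mfap4 also without wild type replicate 2 (-1.77) or Dnmt1 CKO replicate 2 (-2.88). Mfap4, at 2208 and 3071 CPM in wild type, is on the list of matrix fibroblast markers, and at Leiden resolution 2.0 the lymphatic cluster held only 6, 9, 13 and 14 cells. Without the 4 libraries in turn 37, 11, 43 and 32 genes were called.

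In immune-like cells 2 of 12557 genes were called. Ifi44l, an interferon-induced gene, had 190 UMIs in wild type and 0 in Dnmt1 CKO, at least 109-fold lower (adjusted p = 0.015). The histidine-degrading enzyme gene Hal had 139 and 3, a ratio of 79.8 (26.8 to 392; adjusted p = 0.015). Neither was called without wild type replicate 1 or wild type replicate 2, when 0 genes were called, nor with sex as a covariate or equal cells per library, while 510 and 218 were called without Dnmt1 CKO replicates 1 and 2. Dazl had 0 and 156 UMIs (at least 30.2-fold higher) and was not called (adjusted p = 0.103), but was called under 7 of 16 alternatives, among them without Dnmt1 CKO replicate 1 or Dnmt1 CKO replicate 2, by DESeq2 and with doublets kept. Of 40 lists 13 were called, 0 with an estimated correlation, where 0 lay at an unadjusted p under 0.05 and each adjusted p was at least 0.876, and 0 by fry. The median of 27 interferon response genes was -0.52 (adjusted p = 0.00299) and that of 6 haemoglobins 1.44 (3.16e-06). Neutrophil markers had a median of -1.56 (0.000456), a call lost without wild type replicate 1. Neutrophil-like cells were 51 of 614 and 37 of 555 immune-like cells in wild type and 28 of 872 and 20 of 914 in Dnmt1 CKO. That mix shifted the same way as the neutrophil markers, so a change per cell was not told apart from it.

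The change between genotypes in the sums of mesenchymal-like cells differed from that in other classes by the interaction test. It did so in 640 of 17743 genes against epithelial-like cells (365 up, 275 down) and in 1086 of 16390 against endothelial-like cells (501 up, 585 down). Of these 482 and 678 were also called in mesenchymal-like cells themselves. The mesenchymal-like clusters parted by genotype, so a different response per cell was not told apart from a change in the mix of cells. Trim5 rose by 5.48 in mesenchymal-like cells and had values of 0.34 in epithelial-like and 0.75 in endothelial-like cells, and Mme fell by 2.95 and had a value of 0.08 in epithelial-like cells. Without wild type replicates 1 and 2 the counts were 164 and 110 against epithelial-like cells and 700 and 585 against endothelial-like cells, and without Dnmt1 CKO replicate 2 they were 1343 and 1737.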

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

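These results were all planned, and each rests on a test of the difference between cell classes. The change in mesenchymal-like cells differed from that in epithelial-like cells for 640 genes and from that in endothelial-like cells for 1086 genes. These are changes in sums over each class. A change in the mix of mesenchymal-like cells, whose clusters parted by genotype, was not told apart from a change per cell.

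Against epithelial-like cells, the difference on the log2 scale was 8.75 for the X-linked Trap1a (SE 1.43, adjusted p = 0.0236), 5.04 for the antiviral gene Trim5 (SE 0.371, adjusted p = 0.00209) and 4.64 for AI662270 (SE 0.792, adjusted p = 0.0243). It was -3.12 for Nebl (SE 0.189, adjusted p = 0.00174), which had a value of 0.83 in epithelial-like cells, -3.05 for Mme (SE 0.214, adjusted p = 0.00174) and -2.56 for Gsto1 (SE 0.363, adjusted p = 0.031), at -1.25 in mesenchymal-like and 1.31 in epithelial-like cells. Not called were AI662270 (3.84) and Trap1a (8.13) without wild type replicate 1, AI662270 (5.31) and Trap1a (10.73) without wild type replicate 2, and Gsto1 without Dnmt1 CKO replicate 1 (-2.56) and Dnmt1 CKO replicate 2 (-2.54).

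Against endothelial-like cells, the difference was 9.76 for Trap1a (SE 1.64, adjusted p = 0.0073), a call lost without wild type replicate 2 (6.71), 7.21 for AI662270 (SE 0.379, adjusted p = 4.51e-07) and 4.59 for Trim5 (SE 0.542, adjusted p = 0.000713). It was -2.62 for Thsd7a (SE 0.292, adjusted p = 0.000242), -2.51 for the insulin-like growth factor binding gene Igfbp5 (SE 0.383, adjusted p = 0.0107) and -2.49 for Lpin1, a phosphatidic acid phosphatase (SE 0.246, adjusted p = 0.000273). Igfbp5 rose by 3.09 in endothelial-like cells (SE 0.35, adjusted p = 0.00134) and had a value of 0.66 in mesenchymal-like cells, where it was not called (adjusted p = 0.136). The wild type counts of Trap1a lay at or under 3 UMIs, so its difference depends on the prior count.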

How the results depend on the processing

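Sex as a covariate and clustering again without called genes were chosen after seeing the data. Dnmt1 in mesenchymal-like cells was called under each of the 16 alternatives, from -1.55 to -1.05 with libraries left out. Its fall in mesothelial-like cells missed the threshold with DESeq2 (-1.96), the stricter cell filter (-1.78) and equal cells per library (-2.34), and ranged from -2.39 to -1.65 with libraries left out. In matrix fibroblast-like cells Dnmt1 turned from 0.06 to -1.50 (adjusted p = 0.00116) at Leiden resolution 0.5 and -1.11 (0.0299) at 2.0, where other cells bear that name. A library left out leaves 2 against 1, so the lone library is assumed to vary like the other group. Genes called then ranged from 1180 to 2351 in mesenchymal-like, 0 to 81 in epithelial-like, 0 to 101 in endothelial-like, 0 to 510 in immune-like, 14 to 222 in mesothelial-like, 114 to 398 in matrix fibroblast-like, 32 to 535 in adventitial fibroblast-like, 43 to 265 in myofibroblast-like, 70 to 375 in pericyte-like, 1 to 131 in alveolar type 1-like, 0 to 133 in alveolar type 2-like and 11 to 43 in lymphatic endothelial-like cells. Interaction genes ranged from 110 to 1343 (epithelial-like) and 585 to 1737 (endothelial-like), lists called from 7 to 13, 11 to 25, 10 to 24, 15 to 18 and 12 to 16 (mesenchymal-like, epithelial-like, endothelial-like, immune-like, mesothelial-like), classes called by share from 0 to 5 (broad) and 0 to 6 (subclasses), and the Mki67 or Top2a difference from 4.29 to 7.52 percentage points (9.06 unthinned).

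The labels do not say that replicate numbers pair the libraries, and 2 pairs are too few to settle it. Deviations of libraries with the same number correlated across genes, which are not independent, at 0.0964 in mesenchymal-like, 0.318 in epithelial-like, 0.107 in endothelial-like, -0.0454 in immune-like and -0.0721 in mesothelial-like cells (0.181, 0.39, 0.181, 0.0107 and -0.0466 without sex-linked genes). With the replicate number as a block, 3811 mesenchymal-like, 249 epithelial-like, 152 endothelial-like, 19 immune-like, 461 matrix fibroblast-like, 610 adventitial fibroblast-like, 223 myofibroblast-like, 139 alveolar type 1-like and 155 alveolar type 2-like genes were called.

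Counts that moved by over 1.5 times are given in the order of the classes above, and the cause was not tested. With no low-count filter they were 128 epithelial-like, 95 endothelial-like, 177 immune-like, 241 mesothelial-like, 278 matrix fibroblast-like, 218 myofibroblast-like, 84 alveolar type 1-like, 92 alveolar type 2-like, 22 lymphatic endothelial-like and 2054 and 1654 interaction genes. With sex as a covariate they were 1477 mesenchymal-like, 2 epithelial-like, 0 immune-like (edgeR, 514 at an unadjusted p under 0.05), 216 mesothelial-like, 171 matrix fibroblast-like, 11 myofibroblast-like, 1 alveolar type 1-like and 7 alveolar type 2-like. DESeq2 called 20 epithelial-like, 33 immune-like, 211 adventitial fibroblast-like, 109 pericyte-like and 13 alveolar type 2-like genes. With equal cells per library they were 5 epithelial-like, 3 endothelial-like, 0 immune-like, 13 mesothelial-like, 42 matrix fibroblast-like, 149 pericyte-like, 5 alveolar type 1-like and 14 alveolar type 2-like, and with doublets kept 1 epithelial-like, 33 endothelial-like, 4 immune-like, 29 alveolar type 1-like, 26 alveolar type 2-like and 74 lymphatic endothelial-like. The stricter cell filter called 1 epithelial-like gene and library-size scaling 160 matrix fibroblast-like genes. In pericyte-like cells library-size scaling turned 153 up and 113 down into 153 up and 205 down. At Leiden 0.5 they were 2845 matrix fibroblast-like, 136 adventitial fibroblast-like and 716 myofibroblast-like, at 2.0 they were 1056, 108 and 690, and clustered without called genes 708, 149, 540 and 1351 pericyte-like. The last count is from a class that took in a cycling cluster. TMM on cell counts called 1 broad class. With an estimated correlation camera called 0 lists in each of the 5 classes, and fry called 3 in mesenchymal-like, 1 in mesothelial-like and 0 in the other classes.

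For named genes, 1974 results under the other alternatives kept direction and side of the threshold, 72 came to be called, 67 were no longer called and 2 turned; with libraries left out 540 did, 27 came to be called and 137 were no longer called. For lists these were 203, 7 and 46, and 231, 16 and 7 with libraries left out; single lists were followed for all of mesenchymal-like cells and for 4 lists in each other class. In simulations of 2-fold changes edgeR called from 0.0% (lymphatic endothelial-like) to 44.9% (adventitial fibroblast-like) of the changed genes, with 34.4% in mesenchymal-like and 12% in epithelial-like cells, so changes of this size are often missed in each class.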

Other observations

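Of the tests below, those of cells that kept Dnmt1 and of wild type cells mixed in were chosen after the result they concern was seen. Beyond the classes compared, a cycling cluster held 83 and 23 wild type and 211 and 152 Dnmt1 CKO cells. The number of smooth muscle-like cells hung on the clustering, with 18, 30, 319 and 267 cells at Leiden resolution 1.0, 15, 32, 25 and 33 at 2.0 and 28, 39, 28 and 43 when clustered without called genes. In the latter 2 clusterings a mutant-heavy cluster (3, 2, 306 and 242 cells, and 7, 5, 300 and 213) bore the name myofibroblast-like. In the cycling cluster Dnmt1 stood at 109 and 106 CPM in wild type and 20.5 and 34.1 CPM in Dnmt1 CKO. In the cluster made up almost wholly of mutant cells it stood at 5.35 and 4.17 CPM. Erythroid-like cells, of which there were 28, 26, 64 and 21, held 786 and 1100 CPM of germline transcripts in Dnmt1 CKO and 0 and 20 CPM in wild type. Mesenchymal marker transcripts were also found in them, at 12760 and 7307 CPM in wild type and 7496 and 11910 CPM in Dnmt1 CKO, against 20190, 19800, 15100 and 16870 CPM in mesenchymal-like cells.

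Dnmt1 CKO cells in the matrix fibroblast-like clusters held few germline transcripts, 346 and 81.9 CPM against 1585 and 1599 CPM in the other mesenchymal-like cells of the same libraries pooled; the sum was also low in Dnmt1 CKO replicate 2 in myofibroblast-like (852 and 134 CPM) and pericyte-like cells (1293 and 618 CPM). Shallow sequencing is argued against, since at 3000 UMIs per cell the share of cells with a germline UMI was 29.8% and 11.2% against 89.0% and 78.6%, a gap of at least 59.3 percentage points. Within the matrix fibroblast-like clusters 35 called genes had fallen to below 50% of their wild type level. They cannot decide whether wild type cells were mixed into the suspension, since the mix of cells differed. Nppc, Mme, Gpx3 and Prkg2, among them, were also leading genes of a matrix fibroblast-like cluster at Leiden resolution 2.0. That cluster held 466 and 661 wild type and 2 and 30 Dnmt1 CKO cells. Cells that kept Dnmt1 also remain open as a candidate explanation, since Dnmt1 in the matrix fibroblast-like clusters at resolution 1.0 reached at least 91.1% of the wild type level in both libraries. The clusters were built from genes that include germline genes, so part of this difference may come from the clustering itself.

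In Dnmt1 CKO replicate 1, mesenchymal-like cells held both Y-linked transcripts (212 CPM) and Xist (1910 CPM), the X-inactivation RNA, whereas mesenchymal-like cells of wild type replicate 2, also male, held 0.0497 CPM of Xist. A mixture of male and female cells is argued against, since Xist in the epithelial-like, endothelial-like and immune-like cells of that library reached at most 3.61% of its level in wild type replicate 1. Xist made in male cells that lost Dnmt1 may explain it: of cells with a Y-linked UMI 70.5% held a Xist UMI, and of those without 68.6%. Xist and Tsix overlap on opposite strands, and how the counting used the strand was not given. The presence of Xist beside Y-linked transcripts concerns a single library, so it cannot be set against the spread between animals. Mesothelial-like cells of that library also held Xist, at 553 CPM. In the female libraries, wild type replicate 1 and Dnmt1 CKO replicate 2, Xist was 1540 and 3530 CPM in mesenchymal-like and 763 and 1680 CPM in mesothelial-like cells. It was 595 and 890 CPM in epithelial-like, 1090 and 1430 in endothelial-like, 1030 and 1120 in immune-like and 1650 and 1800 in matrix fibroblast-like cells.

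Epithelial-like, endothelial-like and immune-like cells of the mutant libraries held germline transcripts at 18.3 to 62.6 CPM. At most 0.746% of cells in any of these classes held 3 or more different germline genes at 3000 UMIs. That share alone cannot decide whether a subset of them lost Dnmt1. Their germline CPM was 1.2% to 4.59% of that in mesenchymal-like cells, of which only 47.9% and 40.9% held 3 such genes. A subset holding all of it would thus also give few such cells in these classes. Cells with 3 or more such genes held 71.6% and 78.0% of the germline UMIs in Dnmt1 CKO mesenchymal-like cells, against 0.0% to 22.8% in these classes. These values argue against a subset with the germline content of mesenchymal-like cells that holds all of these transcripts. They do not decide on a subset with fewer per cell or one that holds only part of them. Free RNA from mesenchymal-like cells may be the source, as the germline share was at most 1.89 times the share that mesenchymal markers reached in the same cells. Doublets and cells placed in the wrong class cannot be told apart from it, because cells with 3 or more germline genes held up to 22.8% of the germline UMIs.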
